A study of Homo sapiens with 12 samples.

How the data were processed

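The cells were human umbilical vein endothelial cells (HUVECs), primary cells from the inner lining of the umbilical vein, grown to confluence on gelatin-coated dishes. A cone and plate apparatus, in which a turning cone drags medium over the cell layer, applied the shear stress. Per the labels, all cells were first held for 24 h under a steady shear of 15 dyn/cm2 in 1 direction. For the next 6 h the control cultures stayed at 15 dyn/cm2, the nonreversed cultures went to 30 dyn/cm2 in the same direction, and the reversed cultures went to 30 dyn/cm2 in the opposite direction. Each replicate number stands for a set of 3 dishes, 1 per condition, that were started together from a common stock of cells and run side by side. It is called a culture here. There were 4 cultures, and so 12 arrays in 3 groups of 4. Per the labels, the HUVECs came from several suppliers, with 1 supplier and 1 cell line within each set of comparisons. Which supplier served which culture is not given in the sources used here.

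Total RNA was hybridised to the Affymetrix Human Gene 1.0 ST platform, 1 array per dish. The deposited values are on the log2 scale, and the submitters' processing notes name RMA, which corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set. The notes also name limma. The versions, the chip definition and any filter on probe sets are not given in the sources used here. The table holds 21249 probe sets. The platform annotation pairs 18808 of them with 1 gene symbol, 1350 with several and 1091 with none, and no gene is named from a probe set with several. Of the 18808 probe sets with 1 gene identifier, 18783 were found in the RefSeq gene table by that identifier, and 0 symbols needed updating. Every column of the table belonged to 1 of the 12 arrays.

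Array medians lay between 8.26 and 8.33 on the log2 scale, and single values between 2.62 and 13.86. With 4 arrays per group, the number of arrays limits the precision. The values were analysed as deposited, with no further scaling and no filter on dim probe sets. The tests covered 20093 probe sets. Those without a symbol and 65 that hybridise to Y-linked genes, XIST or TSIX were left out. A gene with several probe sets, as 577 genes had, is given by the probe set of highest mean over the 12 arrays, so that gene-list tests covered 18107 genes.

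Each comparison was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 12 arrays, with the group and the culture as terms. Standard errors (SE) and intervals come from this fit. They rest on a spread pooled over all 12 arrays and moderated across probe sets, not on the spread of the differences between single cultures. The culture is a fixed block because the design text describes the 3 dishes of a replicate as a set from the same cells. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and a probe set with an adjusted p under 0.05 is said to have been called. The pairing was checked before any fits were compared. Only arrays of different groups were set against each other. Deviations from the group means correlated between arrays of the same number at 0.629 to 0.802 over 12 pairs, and between arrays of different numbers at -0.464 to 0.303 over 36 pairs. Deviations sum to 0 within a group, which pushes correlations between different numbers below 0 when those of the same number are high. Among arrays of the other groups, all 12 arrays correlated best with an array of their own number. Culture accounted for 74.8% of the sum of squares over probe sets and group for 8.66%.

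A total of 34 gene lists were set against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation between genes was run beside it, as was fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. The lists covered flow-responsive, inflammatory, growth-factor, adhesion, matrix, cell-cycle, stress and metabolic genes and the markers of endothelial and other cell types. Members past the gene-wise test are counted over all probe sets tested and also adjusted over the list alone. The genes named were, per comparison, the 12 largest rises and 12 largest falls among called genes with 1 symbol that moved the same way in all 4 cultures. Where fewer than 5 passed in a direction, the 5 of smallest p in that direction were named as not past the threshold. Any of the 4 members of smallest p in each list could be named too. KLF2, KLF4, NOS3, ICAM1, VCAM1, SELE, CCL2, EDN1, THBD, VEGFA, PLAU, MMP1, CCN1 and CCN2 could be named whatever their values. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined.

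The responses of both arms are measured against the same 4 control arrays, so their chance values are shared. The covariance and correlation of the changes across genes were therefore set beside 100 simulations of unchanged groups against shared controls, in which genes varied independently. They were also computed with the cultures divided 2 and 2, so that the nonreversed and reversed changes shared no array. The steps were tested on simulated data. For reversed against control over 20093 probe sets, 200 seeded changes were put in, of which 95% were called at a log2 size of 0.5 and 100% at a log2 size of 1, with 8 probe sets called that were not seeded. Over 18107 genes, 4 of 4 shifted lists were called with the preset and with the estimated correlation, and 0.1 unshifted lists per simulation were called with the preset correlation. The simulated genes varied independently, so these list rates do not carry over to lists whose genes vary together. In the data the estimated correlation between ATF4 targets, for example, was 0.569. For nonreversed against control with none seeded, 1 of 20093 probe sets was called. A shared variance of 0.0036 put into both arms came back as 0.00360 on average over 20 simulations.

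The alternatives tried were no culture block, a random culture block (duplicateCorrelation), only the 8 arrays of the groups compared, trend and robust settings in eBayes, array weights, array medians subtracted, cyclic loess, only probe sets above the 40th percentile of mean level (7.70 log2), all probe sets of the table, 1 probe set per gene, at least 1.5-fold, each culture left out in turn, camera with an estimated correlation, fry, and the mean of a gene's probe sets. No genomic coordinates are given because the sources used here name no genome build for the table.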

Results

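Transcript levels of HUVECs were measured on 12 arrays, in 4 cultures that each gave 1 control, 1 nonreversed and 1 reversed dish. All dishes were conditioned at 15 dyn/cm2 for 24 h. Over the following 6 h the control stayed at 15 dyn/cm2, the nonreversed dish was raised to 30 dyn/cm2 in the same direction, and the reversed dish was raised to 30 dyn/cm2 and turned in direction. Array medians lay between 8.26 and 8.33 on the deposited log2 scale, and the number of arrays, 4 per group, limits the precision.

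The first comparison asked what a rise in shear did without a change in direction. Thrombomodulin (THBD, probe set 8065353), the endothelial receptor through which thrombin activates protein C, rose by 0.61 ± 0.06 log2 (SE, n = 4 cultures), or 1.52-fold, from 10.55 ± 0.33 to 11.15 ± 0.27 (SD), with an adjusted p of 0.0142. KBTBD8 (probe set 8080911), a substrate adaptor of a cullin ubiquitin ligase, rose by 0.57 ± 0.06 log2, or 1.49-fold (adjusted p = 0.0142). Both were higher in 4 of 4 cultures. They were the only probe sets called by limma in the comparison as designed, 2 higher and 0 lower of 20093. With array medians subtracted the split was 7 higher and 3 lower. At an unadjusted p under 0.05 there were 1916 probe sets, where 1005 would be expected by chance.

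The genes of next smallest p did not pass. Among those higher were the replication licensing factor CDC6, at 0.55 ± 0.07 log2 (SE), the matricellular protein gene CCN3, at 0.48 ± 0.07, and GPAT3, an acyltransferase of triglyceride synthesis, at 0.65 ± 0.09. Among those lower were GBP2, an interferon-inducible GTPase, at -0.65 ± 0.10, the retinaldehyde reductase DHRS3 at -0.51 ± 0.08, the butyrophilin BTN3A1 at -0.45 ± 0.06, ZNF610 at -0.33 ± 0.05 and TFDP2 at -0.32 ± 0.04. Their adjusted p lay between 0.0543 and 0.0594. The probe sets of CDC6 and ZNF610 were dim, not above the 40th percentile of mean level. Endothelial nitric oxide synthase (NOS3) differed by 0.29 ± 0.07, and the flow-induced transcription factors KLF2 and KLF4 by 0.26 ± 0.06 and 0.26 ± 0.07, with adjusted p from 0.168 to 0.248. The leukocyte adhesion receptors E-selectin (SELE), VCAM1 and ICAM1 differed by -0.77 ± 0.16 (adjusted p = 0.147), -0.66 ± 0.15 (adjusted p = 0.192) and 0.10 ± 0.06 (adjusted p = 0.634). Differences of CCL2, EDN1, VEGFA, PLAU, MMP1, CCN1 and CCN2 lay between -0.20 and 0.21. EDN1, the lowest of them, ran from -0.35 to -0.12 over the settings tried, without passing in any. Without the culture block limma called 0 probe sets, with 279 at an unadjusted p under 0.05, and THBD had an adjusted p of 1.00. Leaving out culture 1, 3 or 4 also left 0 calls, with THBD at an adjusted p of 0.147, 0.310 and 0.0510, while 11 were called without culture 2.

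Of the 34 gene lists, 7 were called in this comparison by camera at its preset correlation, 5 upward and 2 downward, and 0 with an estimated correlation or by fry. Targets of ATF4, the transcription factor of the amino acid response, had the largest mean shift, 0.32 log2, with 11 of 12 members higher (adjusted p = 5.52e-07; adjusted p = 0.497 with an estimated correlation). None of the 12 rose past the gene-wise test and 5 did adjusted over the list alone, among them asparagine synthetase (ASNS), at 0.64 ± 0.16 (SE), and the serine synthesis enzymes PSAT1, at 0.63 ± 0.18, and PHGDH, at 0.59 ± 0.19. Interferon-stimulated genes were lower in 16 of 16 members, with a mean of -0.20 (adjusted p = 2.01e-08; adjusted p = 0.496 with an estimated correlation). None fell past the test over all genes and 2 did adjusted over the list alone, IFIT2 (a dim probe set) at -0.36 ± 0.07 and IFIH1 at -0.37 ± 0.08. The median of this list was -0.46 in culture 4 and between -0.13 and -0.07 in the others, and without culture 4 its mean was -0.11, still called (adjusted p = 0.000586). Genes of the negative feedback on ERK signalling were higher in 11 of 12 members, with a mean of 0.18 (adjusted p = 5.84e-06; adjusted p = 0.255 with an estimated correlation). Of these, 0 rose over all genes and 5 adjusted over the list alone, among them the phosphatase DUSP5, at 0.36 ± 0.07.

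The other 4 called lists moved less. NRF2 antioxidant genes had a mean of 0.13, with 0 of 11 past the test and 3 adjusted over the list alone, among them the glutathione synthesis subunit GCLM at 0.28 ± 0.06 and the thioredoxin reductase TXNRD1 at 0.23 ± 0.06 (SE). The list's adjusted p was 5.66e-05, and adjusted p = 0.416 with an estimated correlation. Matrix proteases and their inhibitors had a mean of 0.16, with 0 of 15 past the test and 4 adjusted over the list alone, among them the urokinase receptor PLAUR at 0.39 ± 0.08 and ADAMTS9 at 0.49 ± 0.11 (adjusted p = 0.00339; adjusted p = 0.497 with an estimated correlation). Immediate early genes had a mean of 0.08, with 0 of 17 past the test and 4 adjusted over the list alone, among them DUSP1 at 0.29 ± 0.05 and FOSL1 at 0.28 ± 0.05 (adjusted p = 0.00512; adjusted p = 0.416 with an estimated correlation). NF-kB feedback targets had a mean of -0.08, with 0 of 13 past either count (adjusted p = 0.0437; adjusted p = 0.742 with an estimated correlation). The protease call was lost without the culture block (adjusted p = 0.0806) and without culture 1 (0.0561), the immediate early call without culture 2 (0.0681), and the NF-kB call without the block (0.0891) and without culture 1, 2 or 4 (0.0711, 0.0517 and 0.150, the last with a mean of -0.05). Other divisions of the same arrays into groups of 4 called up to 11 lists. Among those that, like the true one, split the arrays of every culture between the groups, the highest was 7.

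The second comparison set the reversed dishes against the controls. SEMA7A (probe set 7990345), a membrane-anchored semaphorin that binds integrins, rose most, by 1.13 ± 0.11 log2 (SE, n = 4 cultures), or 2.19-fold, from 8.74 ± 0.39 to 9.87 ± 0.56 (SD), with an adjusted p of 0.00166. THBD rose by 1.00 ± 0.06, or 2.00-fold (adjusted p = 0.000159), and the proteoglycan-cleaving proteases ADAMTS4 and ADAMTS9 by 0.84 ± 0.10 and 0.82 ± 0.11 (adjusted p = 0.00584 and 0.00904). The vasoconstrictor gene EDN1 fell by 0.82 ± 0.12 log2, to 0.57 times its control level (adjusted p = 0.0102), and SELE fell by 0.86 ± 0.16, to 0.55 times (adjusted p = 0.0300). In all, 252 probe sets were called, 123 higher and 129 lower, each the same way in all 4 cultures. Their median absolute change was 0.40 log2, and 37 changed by at least 1.5-fold.

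The other large rises were GPAT3, at 0.97 ± 0.09 log2 (SE), the CCR6 ligand CCL20, at 0.87 ± 0.18, the chemerin receptor CMKLR1, at 0.86 ± 0.15, and the secreted glycoprotein gene STC1, at 0.76 ± 0.16. CCN3 rose by 0.76 ± 0.07, KBTBD8 by 0.74 ± 0.06, the KIT ligand KITLG by 0.72 ± 0.10 and DAGLA, a lipase of endocannabinoid synthesis, by 0.68 ± 0.10. The largest fall was in ART4, the carrier of the Dombrock blood group, at -0.95 ± 0.09. The probe set annotated to the microRNA gene MIR146A fell by 0.94 ± 0.13, the retinoic acid receptor RARB by 0.79 ± 0.15, and the interferon-inducible GTPases GBP4 and GBP2 by 0.78 ± 0.12 and 0.69 ± 0.10. The ETS transcription factor ETV1 fell by 0.76 ± 0.10, the noncoding RNA LINC02915 by 0.76 ± 0.15, the serotonin receptor HTR2B by 0.72 ± 0.15, MCTP1 by 0.70 ± 0.10 and RFTN2 by 0.69 ± 0.09. Adjusted p for these 18 genes lay between 0.000630 and 0.0437. The probe sets of MIR146A and HTR2B were dim, not above the 40th percentile of mean level (7.70 log2). Of the fixed genes, ICAM1, VCAM1, CCL2, VEGFA, MMP1 and CCN2 differed by -0.28 to 0.18 without passing, and urokinase (PLAU) by 0.38 ± 0.08 with an adjusted p of 0.0517. Over the settings tried CCN2 ran from -0.34 to -0.16 and VCAM1 from -0.37 to -0.12, without passing in any.

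**Figure D1:**
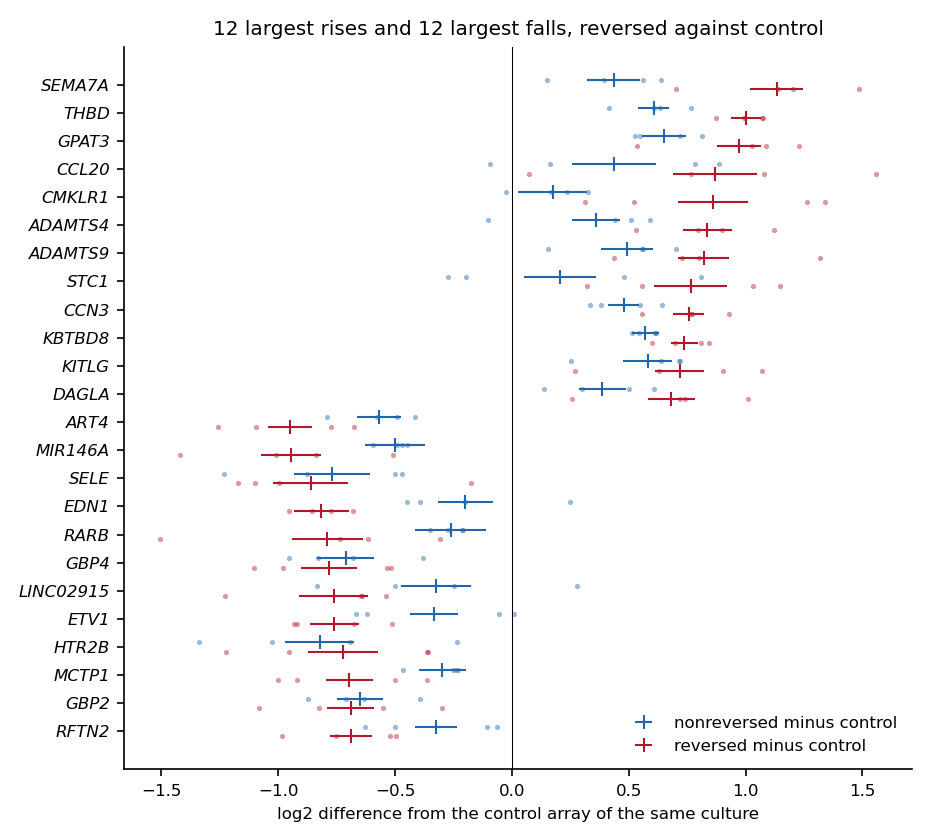
Change of the 12 largest rises and 12 largest falls called in reversed against control, in log2 units on the horizontal axis, with 1 gene per line. Small points are the 4 cultures, each against its own control array, and crosses with bars are means ± SE for the nonreversed (blue) and reversed (red) arms; the reversed means run from -0.95 (ART4) to 1.13 (SEMA7A).

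These calls rested on the pairing of the dishes. Without the culture block limma called 0 probe sets, with 509 at an unadjusted p under 0.05, and all the calls named here were lost. Leaving out culture 1, 3 or 4 lowered the count to 22, 31 and 42, and of the 24 genes with the largest changes 8, 10 and 13 kept their call, against 19 without culture 2. Of all 43 named genes called in this comparison, 9, 11 and 17 kept their call, against 31 without culture 2. THBD, KBTBD8, SEMA7A, GPAT3, CCN3 and ART4 kept it whichever culture was left out.

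By list, 9 of 34 were called by camera in the reversed dishes, 7 upward and 2 downward. None held with an estimated correlation, and 4 of them (the KLF2 and KLF4 programme, proteases, ERK feedback and the unfolded protein response) were among the 5 that fry called. In the KLF2 and KLF4 flow programme 4 of 12 genes rose, namely THBD, KLF4 by 0.47 ± 0.07 log2 (SE), NOS3 by 0.47 ± 0.07 and KLF2 by 0.33 ± 0.06, 0 fell and 8 did not pass, while 5 rose adjusted over the list alone. The list's mean was 0.21 (adjusted p = 5.63e-05; adjusted p = 0.410 with an estimated correlation). Its median was 0.38 in culture 2 and 0.01 to 0.13 in the others. Among matrix proteases and inhibitors 3 of 15 rose, namely ADAMTS4, ADAMTS9 and PLAUR, the last by 0.58 ± 0.08. Adjusted over the list alone 6 rose, and the list's mean was 0.28 (adjusted p = 3.33e-07; adjusted p = 0.260 with an estimated correlation). Of the ERK feedback genes 1 of 12 rose, DUSP5 by 0.62 ± 0.07, and 6 did adjusted over the list alone, among them the ERK pathway inhibitors SPRY4, at 0.43 ± 0.10, and SPRED1, at 0.34 ± 0.09. The list's mean was 0.19 (adjusted p = 3.91e-05; adjusted p = 0.260 with an estimated correlation).

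Of the stress-response lists, the unfolded protein response, ATF4 targets and NRF2 antioxidant genes were called upward, while heat shock genes (mean -0.05, camera adjusted p = 0.296) and p53 targets (0.875) were not called. In the unfolded protein response 1 of 11 genes rose, the chaperone cofactor DNAJB9 by 0.37 ± 0.07 log2 (SE), and also 1 adjusted over the list alone, with 10 of 11 higher and a mean of 0.12 (adjusted p = 4.34e-04; adjusted p = 0.410 with an estimated correlation). ATF4 targets were higher in 12 of 12 members, with a mean of 0.29, 0 past the test and 3 adjusted over the list alone (adjusted p = 2.93e-05; adjusted p = 0.422 with an estimated correlation). Those 3 were MTHFD2 at 0.45 ± 0.12, TRIB3 at 0.56 ± 0.15 and ASNS at 0.60 ± 0.16. Without culture 4 the list's mean was 0.16, still called (adjusted p = 0.0299), with MTHFD2 at 0.29 and ASNS at 0.35. The list's median was -0.19 in culture 2 and 0.20 to 0.71 in the others. NRF2 antioxidant genes had a mean of 0.09 with 0 of 11 past either count (adjusted p = 0.00782; adjusted p = 0.422 with an estimated correlation), and integrins and focal adhesion genes a mean of 0.06 with 0 of 14 (adjusted p = 0.0443; adjusted p = 0.422 with an estimated correlation). Both calls were lost without the culture block (adjusted p = 0.0984 and 0.163), without culture 1 (0.0533 and 0.0726) and without culture 4 (0.101 and 0.207).

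The downward lists were interferon-stimulated and mitosis genes. Of the interferon-stimulated genes 1 of 16 fell, the RNA sensor IFIH1 by 0.43 ± 0.08 log2 (SE), also the single one adjusted over the list alone. The list's mean was -0.15 (adjusted p = 2.02e-04; adjusted p = 0.515 with an estimated correlation). Its median was -0.47 in culture 4, where 16 of 16 members were lower, and -0.07 to 0.00 in the others, and without culture 4 it was not called (mean -0.05, adjusted p = 0.207). Mitosis genes had a mean of -0.10, with 17 of 19 lower and 0 past either count (adjusted p = 0.00286; adjusted p = 0.543 with an estimated correlation). This call was lost without culture 1 (adjusted p = 0.0714), without culture 4 (0.188) and without dim probe sets (0.40), with a mean of -0.05 in both of the latter. Other divisions of the same arrays into groups of 4 called up to 12 lists. Among those that, like the true one, split the arrays of every culture between the groups, the highest was 9.

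Single genes also changed within lists that camera did not call. Among vasoactive mediators 2 of 13 fell, EDN1 and DDAH1, which breaks down an inhibitor of nitric oxide synthase, the latter by 0.38 ± 0.07 log2 (SE). Adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.150, fry adjusted p = 0.0293). Among chemokines and cytokines 2 of 19 rose, CCL20 and IL11, the latter by 0.46 ± 0.08, and 1 fell adjusted over the list alone, CCL2 at -0.19 ± 0.06. SELE was the 1 of 7 inducible adhesion receptors to fall, in a list whose median was 0.06 and mean -0.06, with camera pointing up (adjusted p = 0.671). The matricellular gene CCN1 fell by 0.40 ± 0.07, as 1 of 13 YAP and TAZ targets, with 3 adjusted over the list alone (camera adjusted p = 0.0555). Of the immediate early genes 2 of 17 rose, NR4A1 and DUSP1, both by 0.25 ± 0.05, and 5 did adjusted over the list alone (camera adjusted p = 0.0560). The growth factor PDGFA rose by 0.44 ± 0.08 as 1 of 20 angiogenic factors and receptors, and the chemokine receptor CXCR4 fell by 0.61 ± 0.12 as 1 of 16 Notch and arterial genes. Smooth muscle actin (ACTA2) fell by 0.39 ± 0.06, as 1 of 15 actin and SRF genes and 1 of 9 smooth muscle and mural markers.

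No gene passed over all genes tested in the lists of NF-kB feedback targets, venous genes, candidate mechanosensors, matrix and basement membrane, heat shock genes, or markers of endothelial, fibroblast, leukocyte, erythroid and epithelial cells in the reversed dishes. Their camera adjusted p lay between 0.0705 and 0.994. Adjusted over the list alone 2 matrix genes rose.

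**Figure D2:**
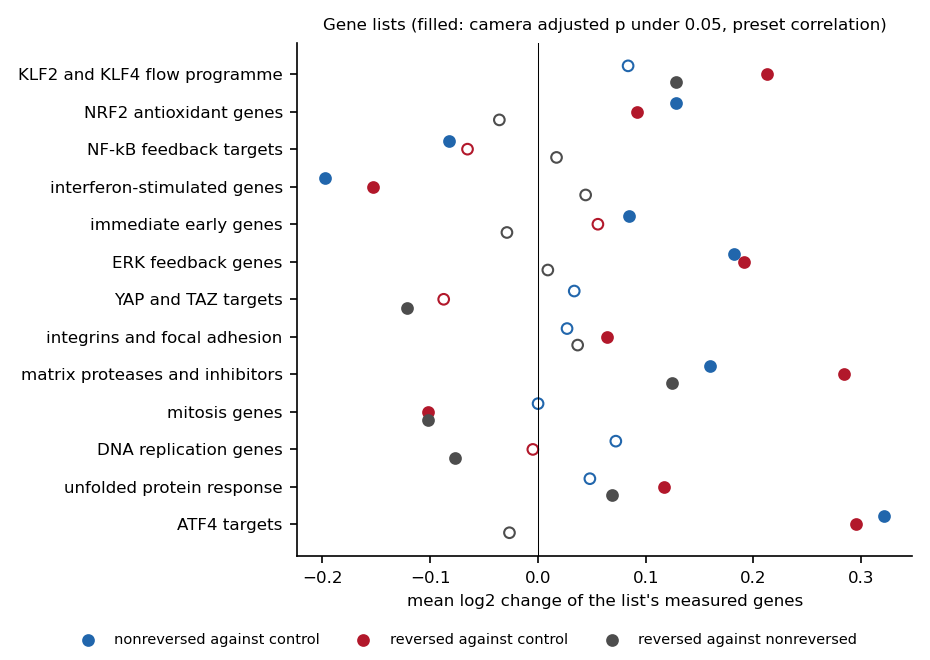
Mean log2 change of the measured genes (horizontal axis) of each list called in at least 1 comparison, in nonreversed against control (blue), reversed against control (red) and reversed against nonreversed (grey). Filled points have a camera adjusted p under 0.05 at the preset correlation; the highest mean is 0.32 for ATF4 targets in the nonreversed arm, and 0 of the filled points stay filled with an estimated correlation.

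The third comparison set the reversed against the nonreversed dishes, both at 30 dyn/cm2, so that flow direction alone differed. SEMA7A, which had the smallest p of the higher genes, differed by 0.70 ± 0.11 log2 (SE, n = 4 cultures), or 1.62-fold, with a 95% interval of 0.45 to 0.95. THBD differed by 0.40 ± 0.06, the proteoglycan VCAN by 0.61 ± 0.10, the metalloprotease ADAM19 by 0.43 ± 0.07 and PLEKHH2 by 0.35 ± 0.06. EDN1 differed by -0.62 ± 0.12, with an interval of -0.87 to -0.36, the translation inhibitor PDCD4 by -0.30 ± 0.05, the WNT agonist RSPO3 by -0.43 ± 0.07, BEND6 by -0.44 ± 0.07 and FAM117B by -0.28 ± 0.05. These 10 genes had the smallest p in their directions and were higher or lower in 4 of 4 cultures, but their adjusted p lay between 0.206 and 0.292. The probe sets of RSPO3 and BEND6 were dim, not above the 40th percentile of mean level. The EDN1 difference was -1.20 in culture 4 and -0.48 to -0.38 in the others, so that it was -0.42 without culture 4. Limma called 0 of 20093 probe sets, with 1350 at an unadjusted p under 0.05 against 1005 expected, and 0 under every other setting run except without culture 2. There a dim probe set of C1D (7934731), named only after its values were seen, was the 1 called, at -0.91 (adjusted p = 0.0122). The probe set that stands for C1D, the brightest of its 3, differed by -0.02 ± 0.06 over all 4 cultures.

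Of the genes fixed beforehand, VCAM1 differed by 0.44 ± 0.15 log2 (SE), CCN1 by -0.35 ± 0.07, CCN2 by -0.29 ± 0.10, KLF4 by 0.21 ± 0.07, NOS3 by 0.18 ± 0.07 and PLAU by 0.17 ± 0.08, with adjusted p from 0.318 to 0.756. VCAM1 was at 0.24 without culture 3 and NOS3 at 0.09 without culture 4. KLF2, ICAM1, VEGFA, SELE, CCL2 and MMP1 differed by -0.11 to 0.06. Among list members, ADAMTS4 differed by 0.48 ± 0.10, the sterol regulator INSIG1 by 0.35 ± 0.08, ANGPT2, the TEK ligand of vessel remodelling, by -0.70 ± 0.19, BMP4 by -0.34 ± 0.07 and DDAH1 by -0.33 ± 0.07, with adjusted p from 0.318 to 0.486.

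Camera called 6 of the 34 lists between the reversed and nonreversed dishes, 3 upward and 3 downward, and 0 held with an estimated correlation or by fry. The KLF2 and KLF4 programme was higher in 10 of 12 members, with a mean of 0.13, 0 past the test and 3 adjusted over the list alone, THBD, KLF4 and the arginine synthesis enzyme ASS1, at 0.34 ± 0.10 log2 (SE) and 0.23 without culture 3 (adjusted p = 8.97e-05; adjusted p = 0.457 with an estimated correlation). Proteases and inhibitors were higher in 14 of 15 members, with a mean of 0.12 and 1 gene, ADAMTS4, adjusted over the list alone (adjusted p = 1.15e-04; adjusted p = 0.457 with an estimated correlation). The unfolded protein response had a mean of 0.07, with 9 of 11 higher and 0 past either count, among them the secreted factor MANF at 0.17 ± 0.06 (adjusted p = 0.00646; adjusted p = 0.699 with an estimated correlation). YAP and TAZ targets were lower in 12 of 13 members, with a mean of -0.12 and 1 gene, CCN1, adjusted over the list alone. The transcription factor TEAD1 differed by -0.14 ± 0.05 in this list (adjusted p = 1.15e-04; adjusted p = 0.457 with an estimated correlation).

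Cell-cycle lists were lower on average in the reversed than in the nonreversed dishes, but not in culture 2. There the median difference was 0.03 for mitosis and 0.02 for DNA replication genes, against -0.22 to -0.08 and -0.17 to -0.01 in the other cultures. Mitosis genes were lower in 16 of 19 members, with a mean of -0.10 and 0 past either count, among them NUSAP1 at -0.25 ± 0.08 log2 (SE) (adjusted p = 4.41e-04; adjusted p = 0.699 with an estimated correlation). DNA replication genes were lower in 14 of 16 members, with a mean of -0.08 and 0 past either count, among them the polymerase clamp PCNA at -0.16 ± 0.06 and TYMS at -0.16 ± 0.07 (adjusted p = 0.00792; adjusted p = 0.699 with an estimated correlation). Without culture 4, the calls of mitosis (mean -0.05, adjusted p = 0.184), DNA replication (mean -0.05, 0.184), unfolded protein response (0.108) and protease genes (0.0579) were lost, and 3 lists were called. DNA replication was also not called without the culture block (0.173) or without culture 3 (0.0619), the unfolded protein response without culture 2 (0.17), nor mitosis without dim probe sets (0.0617). Other divisions of the same arrays called up to 9 lists. Among those that, like the true one, split the arrays of every culture between the groups, the highest was 6.

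The changes of both arms were then set side by side, although they share their control arrays. THBD and KBTBD8 were called in both arms, an overlap of 2. Independent lists would share 0.0122, but these are not independent, because shared controls raise an overlap and a count of same signs, by an amount that was not computed for called probe sets. Of the 252 probe sets called in the reversed arm, 250 had the same sign in the nonreversed arm, 194 of them with an unadjusted p under 0.05 there, and the absolute change was larger in the reversed arm for 237. SEMA7A, for example, was 1.13 ± 0.11 log2 (SE) above control in the reversed arm and 0.44 ± 0.11 in the nonreversed arm. These probe sets were selected by their reversed change, and the direct test between the arms called 0 of them, so the counts of 252 and 2 are not a tested difference. Across the 20093 probe sets the changes had a correlation of 0.653, against 0.501 (0.485 to 0.517) in 100 simulations of unchanged groups, and 70.2% had the same sign, against 66.7%. Genes are not independent replicates, whereas the simulated genes varied independently. The simulated range therefore leaves out the spread that genes varying together would add, and the correlation cannot be judged against it.

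The covariance of the changes was 0.00744, against 0.00268 simulated, a difference of 0.00476. With the cultures divided so that the arms shared no array, the covariance was 0.00407 on average over the 6 divisions, from 0.000629 to 0.00634, and the correlation ran from 0.0293 to 0.346. The 6 divisions use the same cultures. The jackknife standard error of the average, from leaving out 1 culture at a time, was 0.00338, so a shared covariance of 0 cannot be excluded. Without culture 2 the average was 0.00744, and without culture 1 it was 0.00266.

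**Figure D3:**
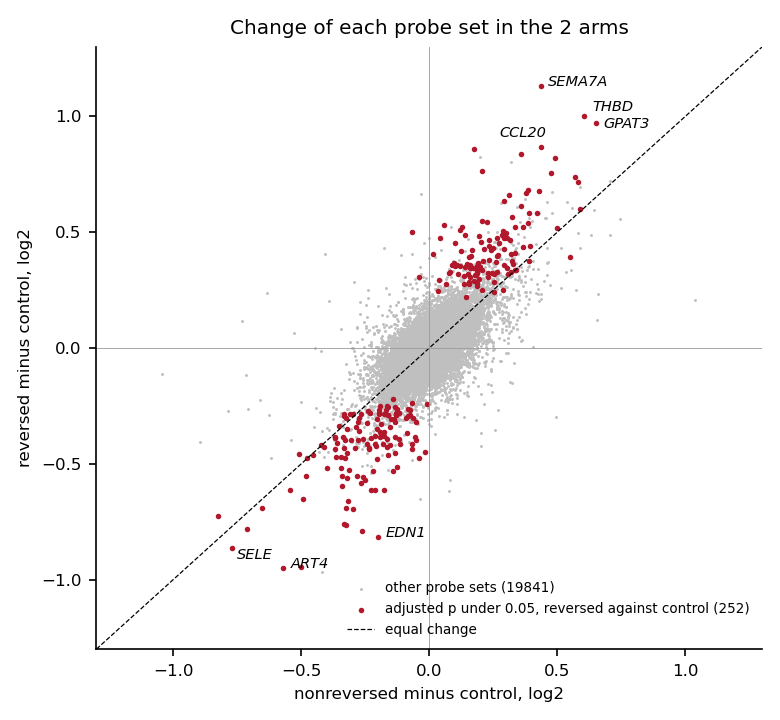
Change of each of 20093 probe sets in the nonreversed arm (horizontal axis) against its change in the reversed arm (vertical axis), both in log2 units against the same control arrays. Red points are the 252 called in reversed against control, of which 250 have the same sign on both axes; the dashed line marks equal change.

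Cultures differed in how far lists moved. The median change of ATF4 targets was 0.29, 0.44 and 0.39 log2 in the nonreversed arm of cultures 1, 3 and 4 and -0.00 in culture 2, where 6 of 12 members were higher. In the reversed arm it was 0.20, 0.48 and 0.71 in those cultures and -0.19 in culture 2, where 3 of 12 were higher. The mean level of ATF4 targets in the control array was 10.99 in culture 2 and 10.09 to 10.61 in the others. Interferon-stimulated genes had their highest control level, 8.24, in culture 4, where their median change was -0.46 in the nonreversed and -0.47 in the reversed arm. The protease list had a median of -0.07 in the nonreversed arm of culture 4, against 0.05 to 0.15 in the others, and of 0.05 to 0.25 in the reversed arm of all 4.

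**Figure D4:**
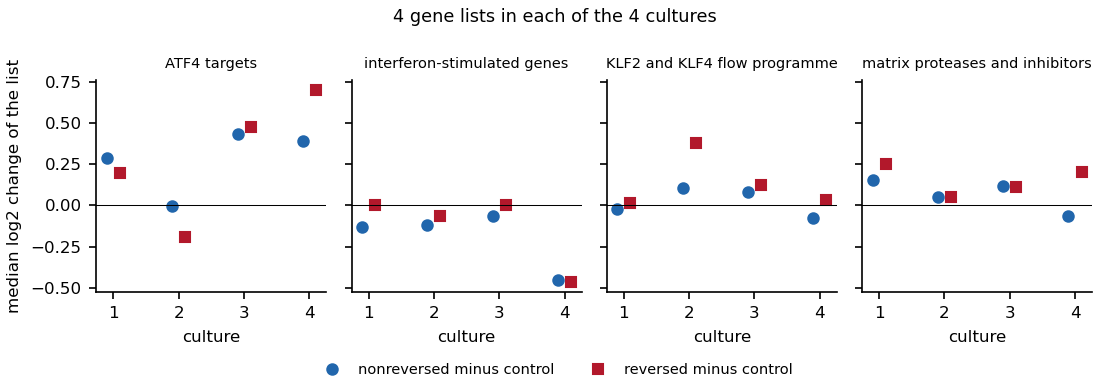
Median log2 change of 4 gene lists (vertical axis) in each culture (horizontal axis), for the nonreversed (blue circles) and reversed (red squares) arms, each against the control array of the same culture. Culture 2 has no upward shift of ATF4 targets (-0.00 and -0.19), and culture 4 has the lowest interferon medians (-0.46 and -0.47).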

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

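The search for cultures that stood apart was fixed beforehand, while among the tests of patterns those on picked genes, on a weaker response of culture 2 and on exchanged control and nonreversed arrays were chosen only after the result was seen. Of 156 gene changes, 22 list medians and 3 groups of array medians, 7 genes, 3 list medians and 1 array median had 1 culture that stood apart from the other 3, and chance alone sets about 1 in 20 such groups apart. In reversed against control these were LINC02915 in culture 2, at -1.23 log2 (others -0.65 to -0.54), KLF2 in culture 3, at 0.37 (0.31 to 0.32), CCL2 in culture 1, at -0.35 (-0.16 to -0.12), MMP1 in culture 4, at 0.36 (-0.04 to 0.01), and DNAJB9 in culture 1, at 0.25 (0.40 to 0.43). In reversed against nonreversed they were EDN1 in culture 4, at -1.20 (-0.48 to -0.38), and FAM117B in culture 1, at -0.20 (-0.31 to -0.30). The median of the interferon-stimulated genes in culture 4 was -0.455 in the nonreversed arm (others -0.128 to -0.0671) and -0.467 in the reversed arm (-0.0671 to 0.00303). Both are measured against the same control array. The median of the unfolded protein response between the arms was -0.000188 in culture 1, against 0.0996 to 0.108 in the others. The median of the control array of culture 4 was 8.33, against 8.29 to 8.30 in the other controls.

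Among the 1091 probe sets without a gene symbol, 7 were called in reversed against control, 5 higher and 2 lower. At an unadjusted p under 0.05 there were 106, against 55 expected.

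Divisions of the arrays compared into groups of 4, 35 in all, were run as planned, so 0 of these tests were chosen after the result was seen. In nonreversed against control, 2 of 35 divisions called at least 2 probe sets, the true one included, and the highest other count was 50. Chance cannot be excluded for that count by this test. The division with 50 does not part all pairs. In cultures 3 and 4 it keeps the true contrast. Both arrays of culture 1 lie in 1 of its groups and both of culture 2 in the other. It is thus not a division free of the treatment, and why its count was higher was not tested. Among the 8 divisions that part all 4 pairs, only the true one called any, and the highest other was 0. In reversed against control, 1 of 35 divisions reached 252, the true one, and the highest other count was 1. The cultures pair the arrays, and of the 8 divisions that part all 4 pairs 1 reached 252, the true one, with 0 as the highest other. These 8 are too few for a share under 1 in 20. The remaining divisions keep both arrays of some cultures in 1 group, so fewer pairs inform their count and they are not a like comparison. In reversed against nonreversed all 35 divisions reached the count of 0, and the highest other was 2. For lists, 6 of 35 divisions reached the 7 of nonreversed against control (highest other 11), 7 of 35 the 9 of reversed against control (highest other 12), and 13 of 35 the 6 of reversed against nonreversed (highest other 9). Among the 8 that part the pairs, 2, 2 and 3 did. Chance cannot be excluded for any of the 3 list counts.

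A larger response in the reversed than in the nonreversed arm was weighed, and the tests on picked genes were chosen only after the result over all genes was seen. The reproducible variance of the change was 0.00567 in the reversed arm (jackknife standard error 0.00417) and 0.00408 in the nonreversed arm (0.00448). By this measure neither can be told apart from 0. The ratio was 1.39, but the difference was 0.998 of its jackknife standard error, so equal responses could give it. With 1 culture left out the lowest ratio was 1.07, which cannot tell whether a single culture carries it, since the ratio's standard error is 0.873. The residual variance of the nonreversed arrays was 0.817 of that of the reversed arrays, so they did not look noisier. That test does not bear on the ratio, because the reproducible variance is the covariance between cultures that share no array. Array noise adds nothing to it on average. The residuals also come from 1 fit to all groups, so each group's value holds some noise of the others. For genes picked in 2 cultures and read in the other 2, reversed minus nonreversed was on average 0.103 if picked by the reversed arm, 0.0312 if picked by the nonreversed arm (-0.0279 to 0.0843 over 6 divisions) and 0.0728 if picked by both, where the lowest was 0.00174, above 0 but by less than the spread, so equal responses cannot be told apart there.

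The ATF4 pattern, in which targets were higher in cultures 1, 3 and 4 and not in culture 2, was found in the data, and of its tests that of a weaker response of culture 2 was chosen only after the result was seen. Levels already high in the control of culture 2 could give it, since that control lay 0.378 log2 above the next highest. The changes in culture 2 are measured against that same array, so a high value in it lowers them whatever its cause. That excess therefore cannot decide between causes. A weaker response of culture 2 in all genes could keep the targets from rising there, but would not by itself bring their median below 0. In the reversed arm of culture 2 that median was -0.19, with 3 of 12 members higher, from 1 pair of arrays. Probe sets called without culture 2 changed there 0.305 times as much as in the others. That is lower than the same kind of selection gave for the other cultures (for the 250 of smallest p in reversed against control without each culture in turn, 0.304 in culture 2 and 0.669 to 0.918 in the others). The KLF2 and KLF4 list, however, moved most in culture 2. In nonreversed against control the same selection gave 0.111 in culture 2, where 57.6% had the same sign, and 0.523 to 0.803 in the others, where 82.4% to 84.8% did. A noisy control array could not be told apart, since the other 3 control levels spread over 0.522 log2, more than that excess of 0.378. With 1 control array per culture, the culture's own level and the error of its array cannot be separated.

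In culture 4 the nonreversed change was smaller in the 252 probe sets called in reversed against control, and of the tests here that of exchanged control and nonreversed arrays was chosen only after the result was seen. The median was 0.163 in culture 4, against 0.231 to 0.269 in the others, but over all probe sets culture 4 did not stand out, with an SD of the nonreversed change of 0.171 (others 0.142 to 0.188). Exchanged control and nonreversed arrays would turn the slope of its nonreversed change on that of the other cultures negative, and at 0.535 it argues against an exchange, although culture 2 was at -0.0204 and cultures 1 and 3 at 0.412 and 0.619. Exchanged nonreversed and reversed arrays would likewise turn the slope of the difference between arms negative. That slope was 0.194, with -0.0141 to 0.343 in the others, which argues against this exchange too, although by less.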

How the results depend on the processing

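Counts of called probe sets against control depended on the settings, and the cause was not tested. Nonreversed against control had 2 calls. It had 0 without the culture block, 0 with a random block, 7 with only the 8 arrays compared, 43 with trend and robust settings, 36 with array weights, 10 with array medians subtracted, 47 without dim probe sets, 13 with 1 probe set per gene and 1 at 1.5-fold or more. With 1 culture left out it had 0 to 11. Reversed against control had 252 calls. It had 0 without the culture block, 83 with a random block, 67 with the 8 arrays, 405 with trend and robust settings, 439 without dim probe sets, 37 at 1.5-fold or more, and 22 to 273 with 1 culture left out. Reversed against nonreversed had 0 calls under every setting and 0 to 1 with 1 culture left out.

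Lists called went from 7, 9 and 6 to 0, 0 and 0 with an estimated correlation and to 0, 5 and 0 by fry, in the order nonreversed against control, reversed against control and reversed against nonreversed. With 1 culture left out, reversed against nonreversed had 3 to 8. The split covariance of the arms, 0.00407, ran from 0.00266 to 0.00744 with 1 culture left out.

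Of single results, 8 reversed sign, all small and not past the threshold. CCN2 in nonreversed against control was 0.01 and became -0.0157 with cyclic loess, -0.00829 without culture 3 and -0.11 without culture 4 (leave-one-out range -0.11 to 0.0908). MMP1 in reversed against control became -0.0116 without culture 4 (range -0.0116 to 0.124). In reversed against nonreversed VEGFA became -0.0169 without culture 2 and -0.0217 without culture 4 (range -0.0217 to 0.0523), SELE 0.11 without culture 4 (range -0.23 to 0.11) and MMP1 -0.0508 without culture 4 (range -0.0508 to 0.0660). Other named-gene results stayed the same in 605, 725 and 539 cases, became weaker in 10, 208 and 0 and stronger in 51, 25 and 0. List results stayed in 88, 116 and 75 cases and became weaker in 24, 28 and 21, with 0 reversed.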

Other observations

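Within lists that camera did not call in reversed against control, single genes of sterol synthesis, cell death and DNA replication changed. INSIG1, which holds back sterol synthesis, rose by 0.66 ± 0.08 log2 (SE, n = 4 cultures; adjusted p = 0.00660), as the only 1 of 12 cholesterol synthesis genes to pass (camera adjusted p = 0.521). The death receptor FAS rose by 0.32 ± 0.06 (adjusted p = 0.0300), as 1 of 9 p53 targets, and SESN1 in the same list fell adjusted over the list alone, at -0.22 ± 0.05 (camera adjusted p = 0.875). CDC6, by a dim probe set, rose by 0.39 ± 0.07 (adjusted p = 0.0296) while the helicase subunit MCM7 fell by 0.25 ± 0.05 (adjusted p = 0.0307). Thus 1 of 16 DNA replication genes rose and 1 fell, with a list median of 0.01, a mean of -0.00 and a camera adjusted p of 0.760. None of the 15 glycolysis and hypoxia genes passed, and 2 rose adjusted over the list alone, among them hexokinase HK2 at 0.28 ± 0.06 (camera adjusted p = 0.380). Of the 11 TGF-beta targets 0 passed, and ANGPTL4, at 0.61 ± 0.14, rose adjusted over the list alone (camera adjusted p = 0.198). Of the 15 BMP and ALK1 targets 0 passed and 2 fell adjusted over the list alone (camera adjusted p = 0.122).

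Median, mean and camera pointed different ways in some lists that were not called, so these have no settled direction. For chemokines and cytokines in reversed against control the median was -0.01 and the mean 0.01, and for epithelial markers the median was -0.07 and the mean 0.00. In nonreversed against control the adhesion receptors had a median of 0.05 and a mean of -0.14.

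ATF4 targets were at 10.85 in the reversed and 10.98 in the nonreversed array of culture 2, beside 10.48 to 10.95 in the treated arrays of the other cultures, while its control, at 10.99, lay above the other controls (10.09 to 10.61). Levels that all approach the same value under raised shear could give that pattern, with an excess of 0.378 log2 in the control of culture 2. An error of that control array could give it as well, since the changes are measured against it. Repeat control dishes of the cells used for culture 2 would help to tell these apart. A time course of ATF4 protein with amino acid levels in the medium would separate shear from medium use.

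SEMA7A and EDN1, which differed between flow directions at 30 dyn/cm2 by 0.70 and -0.62 log2 without passing the threshold, could be measured by PCR in new cultures. A 4th condition, reversed flow kept at 15 dyn/cm2, would show the turn without the rise in shear. More cultures would sharpen the comparison of the arms, since equal responses in both could not be excluded here (0.998 of a jackknife standard error).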
